A study of Mus musculus with 12 samples.

How the data were processed

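Messenger RNA was measured by sequencing in 12 libraries of primary mouse keratinocytes. The cells came from tail skin of K14-SmoM2 mice, in which tamoxifen switches on an active form of the Hedgehog receptor component Smoothened in keratin 14 expressing epidermis, a mouse model of basal cell carcinoma. Per the labels' protocols, the cells were isolated 5 weeks after tamoxifen and grown in a low-calcium medium (60 µM calcium). They received either small interfering RNA pools at 8 pmol per cm2 in a lipid carrier, or adenovirus at a multiplicity of infection of 25, a day after plating, and were harvested 48 h later. RNA was taken with TRIzol and poly(A) libraries were made with a TruSeq mRNA kit, per the labels' protocols. The labels give 4 groups with 3 libraries each, lettered A, B and C: siControl, siYAP1+TAZ, Ad-GFP and Ad-TEADi, an adenovirus carrying an inhibitor of the TEAD transcription factors. Nothing in the labels says that the 3 libraries of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

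The authors deposited a table of CPM values (read counts scaled to a common library size) for 17090 genes in the 12 libraries, scaled by the trimmed mean of M-values (TMM) per the file's name. No library holds a value of 0, and the lowest value in each lies near the CPM of a single read. How genes without reads in some library were handled is not given in the sources used here. If they were left out, genes switched fully on or off cannot be seen, even without a filter on low values. The authors' deposited second table holds, for the same genes, a linear ratio with its fold change for each of the siYAP1+TAZ and Ad-TEADi comparisons. The p-value and adjusted p-value columns of that deposited table are the authors' own, and the test that made them is not given in the sources used here. Per the submitters' processing notes, the tools were cutadapt 1.18, STAR 2.7.0f and Partek 8.0.19.0819 and the genome build was mm10. The counting rule, its use of strand and its treatment of reads shared between gene copies are not given in the sources used here, so genes with near-identical copies (the prolactin family members Prl2c2 and Prl2c3, the Sprr2 and Lce3 families) are uncertain. Gene positions are those of the deposited tables on mm10, with 1 subtracted from the end: 17073 of the 17090 genes (99.9%) then had the start and end of the GENCODE vM21 annotation.

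Depth was read from the low values. In each library the lowest values lay on steps that fit a fixed CPM per read, and the column total divided by that step gave 20.02 to 29.12 M reads per library. Between 83.4% and 85.5% of low values lay within 0.1 read of a whole multiple, short of the 95% set as the minimum for turning the values back into whole reads. The count models planned for that case were therefore not run, and all tests used the deposited CPM values.

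Tests were made with limma 3.58.1 in R 4.3.3 on log2(CPM + 1), so the pseudocount was 1 CPM and log2 fold changes of low genes are understated. Genes with at least 1 CPM in at least 3 of the 12 libraries were kept, which left 12966 genes and set aside 4124. All 12 libraries entered 1 fit with a mean per group and a shared, mean-dependent estimate of spread (eBayes with trend). The contrasts were siYAP1+TAZ against siControl, Ad-TEADi against Ad-GFP, the difference between these effects, and Ad-GFP against siControl. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. A count of 2-fold changes takes the genes that passed with at least a 2-fold change on that scale. The main comparisons have separate control libraries, so no correction for shared controls was needed. Before the data were examined, the groups, the contrasts, the tests, the gene lists, the rule for named genes and most alternatives were fixed.

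The 25 gene lists, written from textbook knowledge, covered YAP/TAZ-TEAD targets, Hedgehog pathway targets, basal keratinocyte, spinous differentiation, cornified envelope, lipid barrier synthesis, DNA replication and S phase, mitosis, CDK inhibitors and p53 targets, interferon response, keratinocyte activation and inflammation, cytoskeleton and SRF targets, extracellular matrix, Notch pathway, WNT pathway, hair follicle progenitor, cholesterol synthesis, unfolded protein and integrated stress response, hypoxia and glycolysis, and markers of fibroblasts, melanocytes, immune cells, endothelial cells, sebaceous cells, and Merkel and neural cells. Thbs1, Krt15, Krt17, Lgr5, Gas1, Sox9, Notch3 and Sesn2 each stood in a pair of lists. Lists with at least 5 tested members, 23 of the 25, were tested with limma's camera, which asks whether a list's genes moved further than other genes, at a preset correlation between genes of 0.01. Its p-values were adjusted by Benjamini-Hochberg over both main comparisons together, and separately for the difference and for the controls. Camera with a correlation estimated from the libraries, and limma's fry, which asks whether a list's own genes moved to 1 side on balance, were alternatives.

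Named genes followed a rule. In the main comparisons these were Yap1, Wwtr1, Tead1, Tead2, Tead3, Tead4, Gli1, Gli2, Ptch1 and Klf4 whatever their result, then the 5 largest rises and the 5 largest falls among genes that passed with a mean of at least 10 CPM over the 6 libraries and no overlap between groups, and up to 3 members of each list with the largest change among those past the threshold. For the difference the 4 largest values in each direction at a mean of at least 10 CPM were taken, and for the controls the 3 largest in each direction. Unnamed gene models were passed over. Some genes that the rule or a list would name are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

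The alternatives were pseudocounts of 0.1 and 5 CPM, no filter on low values, a filter at a mean of 5 CPM, scaling by column total, scaling by the median of ratios, quantile normalization, a fit of only the 6 libraries compared, the replicate letter as a block, eBayes without trend, robust eBayes, array weights, and each library left out in turn. For the gene lists, 6 of these were added after the data had been seen: the pseudocount of 5 CPM, no filter, the median of ratios, eBayes without trend, robust eBayes and array weights.

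The procedure was tested on simulated data made from the siControl means, as a siYAP1+TAZ against siControl comparison over 12642 genes in which 50 genes were changed at each of 4 fold sizes. It recovered 76% of the genes changed by 1.2-fold and 100% of those changed by 1.5-fold, by 2-fold and by 4-fold, with 14 false calls (6.93% of the calls). The changed genes all had a siControl mean of at least 5 CPM, so recovery near 1 CPM was not tested. In the real comparison 68.9% of genes were called, far more than were changed here, so these shares do not carry over to it. Of 20 random lists, camera called 0 after adjustment and 1 at an unadjusted p under 0.05. Genes were simulated independently of each other, so this check cannot judge the preset correlation for lists of genes that vary together. Libraries of a group were checked for duplicates. On approximate reads, the median chi-square per gene of a replicate pair was 0.715 to 1.23 against 0.455 for sampling noise alone. This argues against repeat sequencing of the same library, but it does not show separate cultures or animals. Each library was counted as its own replicate.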

Results

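Gene expression was measured by poly(A) RNA sequencing in primary keratinocytes from K14-SmoM2 mice, a model of basal cell carcinoma in which the Hedgehog pathway is active in the epidermis. The 12 libraries fell into 4 groups of 3. In 1 experiment the cells received small interfering RNA against Yap1 and Wwtr1, which encodes TAZ (siYAP1+TAZ), or a control pool (siControl). In the other they received an adenovirus carrying an inhibitor of the TEAD transcription factors (Ad-TEADi) or green fluorescent protein (Ad-GFP). YAP1 and TAZ are coactivators that act on genes mainly through TEAD factors. Depth, read from the steps of the low values, was 20.02 to 29.12 M reads per library. The means were 23.0 ± 2.65 in siControl, 27.7 ± 1.39 in siYAP1+TAZ, 24.2 ± 3.80 in Ad-GFP and 22.7 ± 1.27 in Ad-TEADi (SD, n = 3). Expression values are means ± SD in CPM over the 3 libraries of a group. Fold changes are on the log2(CPM + 1) scale, and gene positions are on mm10.

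The first comparison asked what a partial knockdown of Yap1 and Wwtr1, measured in RNA only, changes in these tumour-model keratinocytes. The targeted genes fell: Yap1 (chromosome 9, 7931999 to 8004596) went from 196 ± 9.57 CPM in siControl to 67.1 ± 4.62 CPM in siYAP1+TAZ (SD, n = 3), a log2 change of -1.54 (SE 0.0466; limma with Benjamini-Hochberg adjustment, adjusted p = 4.75e-16). Wwtr1 (chromosome 3, 57455649 to 57575910) went from 55.2 ± 1.96 to 28.1 ± 1.97 CPM, a log2 change of -0.95 (SE 0.052; limma with Benjamini-Hochberg adjustment, adjusted p = 2.52e-12). Most tested genes of terminal keratinocyte differentiation rose, and most of those of the contractile cytoskeleton, the extracellular matrix and the cell cycle fell. These lists passed camera at its preset correlation and not with an estimated correlation (adjusted p = 0.177 to 0.275). The differentiation keratin Krt10 (chromosome 11, 99385254 to 99389364) rose from 43.2 ± 4.77 to 695 ± 70.1 CPM, a log2 change of 3.98 (SE 0.0953; limma with Benjamini-Hochberg adjustment, adjusted p = 3.18e-17). The matrix glycoprotein gene Thbs1 (chromosome 2, 118111876 to 118127133) fell from 2825 ± 89.4 to 396 ± 38.4 CPM, a log2 change of -2.84 (SE 0.0612; limma with Benjamini-Hochberg adjustment, adjusted p = 1.6e-17).

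Rises and falls were ranked among genes with a mean of at least 10 CPM over the 6 libraries and no overlap between groups. The largest rise was that of Krt15 (chromosome 11, 100131758 to 100135928), a keratin of basal and hair follicle bulge cells. Krt15 went from 2.07 ± 0.310 to 52.97 ± 5.16 CPM (log2 change 4.14, SE 0.148). It was followed by Uox, which encodes urate oxidase (3.98, from 3.19 to 65.0 CPM), Krt10, the apolipoprotein gene Apoe (3.74, from 36.5 to 497 CPM) and the epidermal transglutaminase gene Tgm3 (3.55, from 28.0 to 331 CPM). The largest falls were those of the skeletal muscle actin gene Acta1 (-3.94; chromosome 8, 123891769 to 123894751), from 24.8 ± 2.08 to 0.691 ± 0.241 CPM, and the metalloprotease gene Adamts15 (-3.19). They were followed by the prolactin family gene Prl2c3 (-3.12, uncertain because of near-identical copies), Thbs1 and the osteoprotegerin gene Tnfrsf11b (-2.77). Among the TEAD genes, Tead1 and Tead2 fell (-0.92 and -0.52) and Tead3 rose (1.51, from 34.0 to 98.6 CPM). Tead4 was at -0.19 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0114). It no longer passed without siControl C (0.0675) or without siYAP1+TAZ C (0.0735), in a range of 1.26e-05 to 0.0735 over the alternatives. The Hedgehog effectors Gli1 and Gli2 rose, by log2 changes of 1.02 (from 3.64 to 8.42 CPM) and 0.73 (from 18.4 to 31.2 CPM). Ptch1, a Hedgehog receptor and target gene, was at 0.18 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0218). It did not pass without siControl A, siControl C or siYAP1+TAZ A (0.124, 0.0503 and 0.114), and its value was -0.0062 when columns were scaled by their totals (limma with Benjamini-Hochberg adjustment, adjusted p = 0.937, in a range of 0.00521 to 0.937). The transcription factor gene Klf4 (chromosome 4, 55527143 to 55532466), a driver of the epidermal barrier programme, rose from 215 ± 29.0 to 1208 ± 13.8 CPM (log2 change 2.49).

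By list, 22 of the 26 tested YAP/TAZ-TEAD targets fell and 3 rose (23 and 3 adjusted over the list alone). Their median log2 change was -0.76 (camera, adjusted p = 4.08e-07, and adjusted p = 0.104 with an estimated correlation). Examples are Ccn2 (-2.31, from 48.2 to 9.002 CPM) and Amotl2 (-2.05). The 3 that rose were Areg (1.51), Asap1 (0.80) and Nuak2 (0.46), named after their values were seen. In the cytoskeleton and SRF target list 19 of 21 genes fell, including Tagln (-2.24) and Acta2 (-1.73; camera, adjusted p = 9.93e-07, and adjusted p = 0.177 with an estimated correlation). Fhl2 (0.14) and Filip1l (1.12), chosen after their values were seen, rose. In the extracellular matrix list 20 of 27 genes fell and 7 rose (20 and 4 under column totals and under quantile normalization), with Col5a2 at -2.28 and the integrin gene Itgb6 at -1.91 (camera, adjusted p = 0.000264, and adjusted p = 0.177 with an estimated correlation). Counts adjusted over the list alone equalled those over all genes in every list of this comparison except where both are given.

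The spinous differentiation list rose in 18 of its 19 tested members and fell in 0, with a median log2 change of 2.18 (camera, adjusted p = 2.06e-10, and adjusted p = 0.177 with an estimated correlation). It holds Krt10 and the desmosomal cadherin gene Dsc1 (2.89, from 180 to 1340.5 CPM). In the cornified envelope list 29 of 32 genes rose and 0 fell, with a median of 1.90 (camera, adjusted p = 2.06e-10, and adjusted p = 0.242 with an estimated correlation). They include Tgm3, the lipoxygenase gene Alox12b (3.26) and the involucrin gene Ivl (2.69, from 130 to 844 CPM). In the lipid barrier synthesis list 17 of 19 genes rose, among them Cyp4f39 (2.68), Pnpla1 (2.54) and Smpd1 (2.40; camera, adjusted p = 9.09e-08, and adjusted p = 0.177 with an estimated correlation). The ceramidase gene Asah1, chosen after its value was seen, fell by 0.25. In the basal keratinocyte list 15 of 18 genes fell, such as Dst (-1.06) and Itga2 (-0.96; camera, adjusted p = 0.00115, and adjusted p = 0.177 with an estimated correlation). Krt15 and Trp63 (0.45, named after its value was seen) rose. In the keratinocyte activation and inflammation list 17 of 25 genes rose and 7 fell (camera, adjusted p = 0.0149, and adjusted p = 0.275 with an estimated correlation). The wound keratin genes Krt6b and Krt16 rose by 2.33 and 2.10 and the alarmin gene S100a8 by 1.95.

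Cell cycle genes fell by small, uniform amounts. All 30 mitosis genes fell, with a median log2 change of -0.51 (camera, adjusted p = 5.88e-08, and adjusted p = 0.275 with an estimated correlation). Examples are Spc25 (-0.73), Cdk1 (-0.64, from 67.1 ± 0.381 to 42.8 ± 2.80 CPM) and Cenpf (-0.61). Of the 30 DNA replication and S phase genes 28 fell and 0 rose, with Rrm2 at -0.62, Mcm6 at -0.57 and Chaf1b at -0.55 (camera, adjusted p = 1.13e-06, and adjusted p = 0.177 with an estimated correlation). In the hypoxia and glycolysis list 14 of 22 genes rose, with Hk2 at 2.20, Ndrg1 at 1.89 and Egln3 at 1.13 (camera, adjusted p = 0.00115, and adjusted p = 0.279 with an estimated correlation). Pgk1 (-0.17, named after its value was seen) fell. Scaled by column totals, 12 of these 22 rose and 8 fell.

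The other lists did not pass camera in this comparison, with adjusted p from 0.15 to 0.816. In the Hedgehog pathway list 8 of 15 genes rose and 7 fell: Sfrp1 rose (2.61), and the cyclin gene Ccnd2 (-1.35) and Igfbp3 (-1.28) fell. Its median was 0.18 and its mean 0.02, while camera's direction was lower (adjusted p = 0.814). For CDK inhibitors and p53 targets the counts were 6 higher and 9 lower of 19 (camera, adjusted p = 0.521), with Cdkn2a at -1.83, Perp at 1.27 and Btg2 at 1.05. For the interferon response they were 4 higher and 6 lower of 15 (4 and 7 adjusted over the list alone; camera, adjusted p = 0.627), with Mx2 at 3.02, Mx1 at 1.14 and Ddx58 at -0.89. The interferon median was -0.18, the mean 0.07 and camera's direction lower. For the Notch pathway they were 3 higher and 5 lower of 11 (4 and 6 adjusted over the list alone; camera, adjusted p = 0.634), with Notch3 at 1.61, Lfng at -1.02 and Notch2 at 0.97. For the WNT pathway they were 8 higher and 6 lower of 18 (camera, adjusted p = 0.61), with Lgr5 at 1.26, Wnt5a at 1.25 and Wnt3 at 1.01. For hair follicle progenitor genes they were 9 higher and 4 lower of 15 (camera, adjusted p = 0.15). For cholesterol synthesis they were 8 higher and 9 lower of 25 (camera, adjusted p = 0.733), with Sqle at 0.70 and Pmvk at 0.59. For the unfolded protein and integrated stress response they were 9 higher and 10 lower of 22 (camera, adjusted p = 0.816), with Slc7a11 at 1.41, Phgdh at -0.97 and Ppp1r15a at 0.95. The stress list's median was -0.04, the mean 0.08 and camera's direction higher. Scaled by column totals, the genes higher and lower were 5 and 7 for the Hedgehog pathway, 4 and 12 for CDK inhibitors and p53 targets, 3 and 9 for the interferon response, 7 and 8 for the WNT pathway, 4 and 16 for cholesterol synthesis and 7 and 12 for the stress response. Quantile normalization gave 4 and 12 for CDK inhibitors and p53 targets, 4 and 15 for cholesterol synthesis and 13 and 8 for hypoxia and glycolysis.

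Markers of other cell types were few among the deposited genes and mostly low. With siYAP1+TAZ, 4 of 6 tested fibroblast markers were higher and 0 lower (camera, adjusted p = 0.262), and 2 of 6 melanocyte markers were higher and 0 lower (camera, adjusted p = 0.176). Of the fibroblast calls, those of Col3a1 (0.073, in a range of 0.000993 to 0.073 over the alternatives) and Col1a1 (0.208, in a range of 0.00267 to 0.208) were lost without siYAP1+TAZ A (limma with Benjamini-Hochberg adjustment). That of Col1a1 was also lost without siControl A (0.181) or siYAP1+TAZ C (0.0603), and column totals left 3 fibroblast markers and 1 melanocyte marker higher, without Mitf (0.0763, in a range of 0.00203 to 0.0763). Of the rest, 3 of 9 endothelial markers were higher and 2 lower (3 and 1 adjusted over the list alone; camera, adjusted p = 0.751), and 3 of 7 sebaceous markers were higher and 3 lower (camera, adjusted p = 0.814). The melanocyte and macrophage gene Gpnmb rose by 3.27, from 38.8 to 383 CPM. Of 4 tested immune markers Cd68 (1.83, from 9.97 to 38.0 CPM), Lyz2 (0.81) and Itgam (0.46, named after its value was seen) rose while Csf1r fell (-0.66). Of 4 Merkel and neural markers the simple keratin genes Krt8 (-2.14, from 15.1 to 2.64 CPM) and Krt18 (-0.96) fell, as did Mbp (-0.11). The call of Mbp was lost without siControl A (0.105) or C (0.085), without siYAP1+TAZ A (0.0677), B (0.118) or C (0.0653) and without Ad-GFP A (0.0533), in a range of 5.29e-06 to 0.118 over the alternatives (limma with Benjamini-Hochberg adjustment). These last lists were too short for a test.

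Across the 12966 genes tested, 4245 were higher and 4687 lower in siYAP1+TAZ (limma with Benjamini-Hochberg adjustment at 0.05), and 970 and 298 of them by at least 2-fold. Scaling by column totals gave 2822 higher and 7159 lower: the siYAP1+TAZ totals were 1017560 ± 1970 CPM against 890008 ± 7846 in siControl, and that scaling shifted the median of all genes by -0.17.

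**Figure D1:**
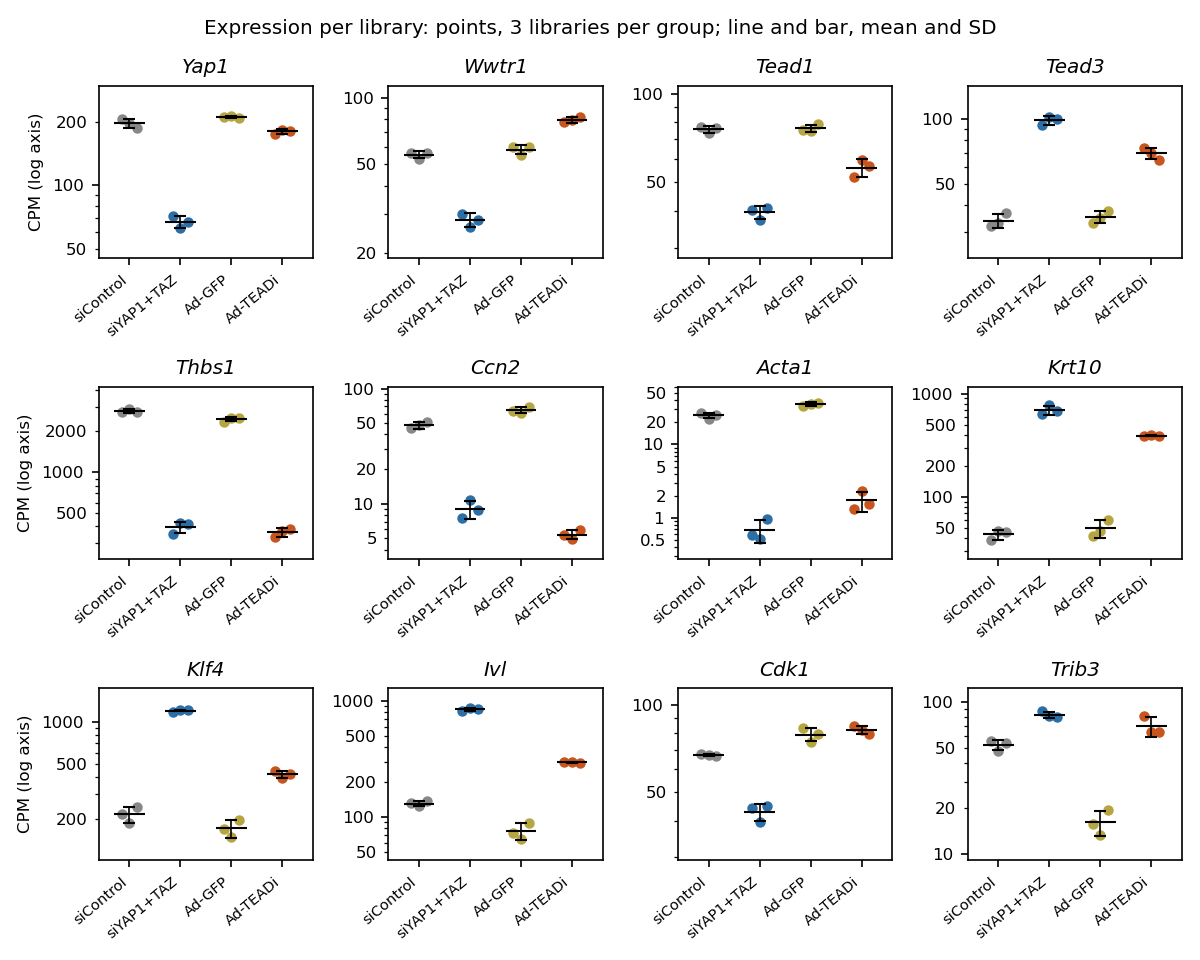
Expression of 12 genes in every library, in CPM on a log axis, by group. Each point is 1 library and the line and bar give the mean and SD of the 3 libraries of a group; Yap1 stands at 67.1 CPM in siYAP1+TAZ against 196 CPM in siControl, and at 180 CPM in Ad-TEADi against 211 CPM in Ad-GFP.

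The second comparison asked what direct inhibition of TEAD changes in the same cells. Here YAP1 and TAZ were not targeted: Yap1 was at 211 ± 2.85 CPM in Ad-GFP and 180 ± 4.30 CPM in Ad-TEADi (SD, n = 3), a log2 change of -0.23 (SE 0.0466; limma with Benjamini-Hochberg adjustment, adjusted p = 0.000311). Wwtr1 rose from 58.2 ± 2.74 to 79.4 ± 2.23 CPM, a log2 change of 0.44 (SE 0.052; limma with Benjamini-Hochberg adjustment, adjusted p = 4.18e-07). Most tested YAP/TAZ-TEAD targets and genes of the cytoskeleton, the matrix and the WNT pathway fell, while most differentiation and integrated stress response genes rose. These lists passed camera at its preset correlation and not with an estimated correlation (adjusted p = 0.104 to 0.365). Ccn2 (chromosome 10, 24595442 to 24598683), a standard readout of TEAD activity, fell from 65.3 ± 3.90 to 5.40 ± 0.467 CPM, a log2 change of -3.37 (SE 0.0888; limma with Benjamini-Hochberg adjustment, adjusted p = 1.28e-16). Krt10 rose from 49.6 ± 9.32 to 393 ± 3.35 CPM, a log2 change of 2.98 (SE 0.0953; limma with Benjamini-Hochberg adjustment, adjusted p = 1.86e-15).

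Among genes with a mean of at least 10 CPM over the 6 libraries, the largest rises were those of Tent5c (chromosome 3, 100451628 to 100489324), a poly(A) polymerase gene, from 0.439 ± 0.120 to 23.5 ± 0.831 CPM (log2 change 4.09), and Efr3b (chromosome 12, 3962554 to 4038915), from 0.358 ± 0.0510 to 21.7 ± 1.17 CPM (4.06). Tcf23 (3.19), the cytochrome P450 gene Cyp2b10 (3.07) and the growth factor gene Areg (2.98, from 16.1 ± 2.92 to 134 ± 12.0 CPM) followed. The largest falls were those of Tnfrsf11b (-3.83; chromosome 15, 54250619 to 54278484), Acta1 (-3.75, from 35.5 ± 1.73 to 1.74 ± 0.528 CPM), the macrophage growth factor gene Csf1 (-3.72; chromosome 3, 107741048 to 107760469; from 171 ± 4.57 to 12.1 ± 0.359 CPM), Tagln (-3.71) and Ccn2. Of the TEAD genes, Tead1 (-0.44) and Tead2 (-1.23, from 5.66 to 1.83 CPM) fell and Tead3 (0.96) and Tead4 (0.55) rose. Gli1 was at 9.08 ± 0.131 and 9.32 ± 1.04 CPM (log2 change 0.03; limma with Benjamini-Hochberg adjustment, adjusted p = 0.773) and Gli2 at 26.3 ± 1.49 and 25.8 ± 1.32 CPM (-0.03; adjusted p = 0.693). Ptch1 fell by 0.23, and Klf4 rose by 1.31, from 170 ± 24.6 to 419 ± 24.6 CPM.

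Of the 26 YAP/TAZ-TEAD targets 20 fell and 4 rose, with a median log2 change of -0.60 (camera, adjusted p = 1.54e-07, and adjusted p = 0.104 with an estimated correlation). Thbs1 fell by 2.76, and the 4 that rose were Areg and, named after their values were seen, Birc5 (0.25), Gadd45a (0.69) and Nuak2 (0.40). In the cytoskeleton and SRF target list 16 of 21 genes fell and 2 rose (17 and 3 adjusted over the list alone), with Myl9 at -2.17 beside Acta1 and Tagln (camera, adjusted p = 4.08e-07, and adjusted p = 0.177 with an estimated correlation). In the extracellular matrix list 21 of 27 genes fell and 4 rose, with the fibronectin gene Fn1 at -2.31 and Col5a2 at -2.24 (camera, adjusted p = 5.88e-08, and adjusted p = 0.11 with an estimated correlation). The Hedgehog pathway list fell in 8 of 15 genes and rose in 2, with Igfbp3 at -1.49, Ccnd2 at -1.16 and Sfrp1 at 0.92 (camera, adjusted p = 0.0156, and adjusted p = 0.177 with an estimated correlation). The WNT pathway list fell in 11 of 18 genes and rose in 3, with the WNT antagonist genes Apcdd1 (-1.62) and Dkk3 (-1.24) and the ligand gene Wnt10b (-1.01) lower (camera, adjusted p = 0.00782, and adjusted p = 0.177 with an estimated correlation). The Hedgehog and WNT lists were both higher in Ad-GFP than in siControl, by medians of 0.45 and 0.28. Their falls were therefore measured from a control that lay above the other one. The basal keratinocyte list fell in 14 of 18 genes and rose in 4, with Postn at -1.42, Dst at -1.10 and Krt15 at 0.90 (camera, adjusted p = 0.000828, and adjusted p = 0.177 with an estimated correlation). The interferon response list fell in 11 of 15 genes and rose in 3, with Gbp2 at -1.51, Ddx58 at -1.33 and Parp14 at -1.18 (camera, adjusted p = 0.00137, and adjusted p = 0.177 with an estimated correlation). The interferon list, too, was higher in Ad-GFP than in siControl, by a median of 0.29, so its fall was measured from a raised control. Gbp2 stood at 1.42 CPM in siControl, 4.46 CPM in Ad-GFP and 0.930 CPM in Ad-TEADi. At a mean of at least 5 CPM this list no longer passed (camera, adjusted p = 0.103, in a range of 0.000392 to 0.103 over the alternatives). Beside Sfrp1 and Krt15, members that moved against these lists, named after their values were seen, included Fhl2 (0.22), Filip1l (0.22), Itga5 (0.11), Mmp10 (1.90), Tgfbi (0.88), Wif1 (0.66), Wnt3 (0.39), Wnt5a (0.89), Itga6 (0.29), Krt14 (0.25), Trp63 (0.19), Mx1 (0.42) and Mx2 (0.80). Counts adjusted over the list alone equalled those over all genes except where both are given.

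The spinous differentiation list rose in 18 of 19 genes, with Ptgs1 at 2.26 and Grhl3 at 1.97, and Pou3f1 (-0.41, named after its value was seen) fell (camera, adjusted p = 1.2e-08, and adjusted p = 0.234 with an estimated correlation). The cornified envelope list rose in 25 of 32 genes and fell in 4 (camera, adjusted p = 3.1e-06, and adjusted p = 0.365 with an estimated correlation). Alox12b rose by 2.90, Tgm3 by 2.59 and Lce3d by 2.59, the last uncertain because of near-identical copies. The 4 that fell, named after their values were seen, were the late envelope genes Lce1a1 (-1.60), Lce1c (-1.45) and Flg2 (-0.50), and Sprr2a3 (-0.16), which has near-identical copies. In the lipid barrier synthesis list 15 of 19 genes rose and 3 fell, with Cyp4f39 at 2.39, Pnpla1 at 2.29 and Elovl4 at 1.74 (camera, adjusted p = 1.08e-05, and adjusted p = 0.241 with an estimated correlation). The 3 that fell, named after their values were seen, were Asah1 (-0.61), Cers4 (-0.35) and Elovl6 (-0.17).

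The unfolded protein and integrated stress response list rose in 20 of 22 genes and fell in 0, with a median log2 change of 0.79 (camera, adjusted p = 4.08e-07, and adjusted p = 0.241 with an estimated correlation). Trib3 rose from 16.1 ± 3.11 to 69.5 ± 10.3 CPM (2.05), the glutathione-degrading enzyme gene Chac1 by 1.54 and the stress transcription factor gene Ddit3 by 1.34. All 22 of these genes were lower in Ad-GFP than in siControl. The hypoxia and glycolysis list rose in 19 of 22 genes and fell in 1, with Ndrg1 at 1.69, Vegfa at 1.48 and Egln3 at 1.17, and Aldoc (-0.27, named after its value was seen) lower (camera, adjusted p = 2.85e-05, and adjusted p = 0.241 with an estimated correlation). The DNA replication and S phase list rose in 18 of 30 genes by small amounts and fell in 1, with Ccne2 at 0.72 and Cdt1 at 0.63, and E2f1 (-0.28, named after its value was seen) lower (camera, adjusted p = 0.021, and adjusted p = 0.424 with an estimated correlation). This call was lost when columns were scaled by their totals (camera, adjusted p = 0.0569, with 11 higher and 5 lower) and under quantile normalization (adjusted p = 0.072, with 14 higher and 2 lower). Its range over the alternatives was 0.0104 to 0.072. For mitosis, 12 of 30 genes were higher and 0 lower (10 and 0 adjusted over the list alone), with Cdc20 at 0.34, Aurka at 0.33 and Ube2c at 0.32, and the list did not pass (camera, adjusted p = 0.0725, in a range of 0.026 to 0.32 over the alternatives). Under column totals and under quantile normalization 6 mitosis genes were higher and 0 lower.

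The remaining lists did not pass camera. Among CDK inhibitors and p53 targets 7 of 19 were higher and 8 lower (8 and 8 adjusted over the list alone; camera, adjusted p = 0.702), with Cdkn2a at -1.09, Mdm2 at 1.04 and Cdkn1a at 0.91. In the keratinocyte activation and inflammation list 12 of 25 were higher and 8 lower (camera, adjusted p = 0.499), with Tslp at 2.38, Krt6b at 2.14 and Slpi at 2.06. Its median was -0.04, its mean 0.37 and camera's direction higher. In the Notch pathway 3 of 11 were higher and 6 lower (camera, adjusted p = 0.362), with Maml2 at -1.08, Notch3 at 1.03 and Nrarp at 0.77. Among hair follicle progenitor genes 4 of 15 were higher and 7 lower (camera, adjusted p = 0.134), with Runx1 at -0.95 and Sox9 at -0.91. In cholesterol synthesis 9 of 25 were higher and 7 lower (9 and 8 adjusted over the list alone; camera, adjusted p = 0.946), with Pmvk at 0.54. Column totals and quantile normalization each gave 5 higher and 11 lower for cholesterol synthesis. Of the markers of other cells, 1 of 6 fibroblast markers was higher (Col3a1 at 0.68, from 0.293 to 1.06 CPM; camera, adjusted p = 0.634), as were 4 of 6 melanocyte markers (Gpnmb at 0.77; camera, adjusted p = 0.228). Of the endothelial markers 3 of 9 were higher and 1 lower (camera, adjusted p = 0.567), and of the sebaceous markers 5 of 7 were higher and 1 lower (Cidea at 2.21; camera, adjusted p = 0.134). Column totals gave 3 and 2 for each of these last lists, and 1 and 10 for the Hedgehog pathway. The immune markers Cd68 (1.47), Itgam (0.79) and Lyz2 (0.67, named after its value was seen) rose and Csf1r fell (-0.85). Krt8 (-1.96), Krt18 (-0.95) and Mbp (-0.25) of the Merkel and neural list fell.

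Across all genes tested, 4339 were higher and 3415 lower in Ad-TEADi (limma with Benjamini-Hochberg adjustment at 0.05), with 508 and 352 changed by at least 2-fold. Scaling by column totals gave 3026 higher and 4740 lower. In the authors' deposited table, at the same threshold over all 17090 genes, 4715 genes were higher and 3660 lower with Ad-TEADi, and 4786 higher and 4919 lower with siYAP1+TAZ. Of the genes tested here, 8768 passed for siYAP1+TAZ in the authors' deposited table, of which 8763 passed here in the same direction and 0 in the opposite one. For Ad-TEADi these numbers in the authors' deposited table were 7571, 7555 and 0.

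The third comparison set the effects side by side, to ask how far TEAD inhibition matches the partial knockdown of its coactivators. Of the 5959 genes that passed in both comparisons, 2690 rose in both (1421 for independent lists of these sizes) and 2283 fell in both (1234 for independent lists). Scaling by column totals turned this balance, with 1780 rising and 3708 falling in both. Opposite changes were fewer than for independent lists: 368 genes rose with siYAP1+TAZ and fell with Ad-TEADi (1118 for independent lists), and 618 did the reverse (1568). At 2-fold or more, 396 rose in both and 182 fell in both, against 38.0 and 8.09 for independent lists, and 4 went opposite ways. Across the 12966 genes the log2 changes had a Pearson correlation of 0.71 and a Spearman correlation of 0.60, as a description, since genes are not independent replicates. The YAP/TAZ-TEAD target list did not pass the test of the difference: 6 of its 26 genes had a higher and 9 a lower effect with siYAP1+TAZ than with Ad-TEADi (camera, adjusted p = 0.654). Among its members, Ccn1, named after its values were seen, fell by 1.69 with siYAP1+TAZ and by 1.68 with Ad-TEADi.

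**Figure D2:**
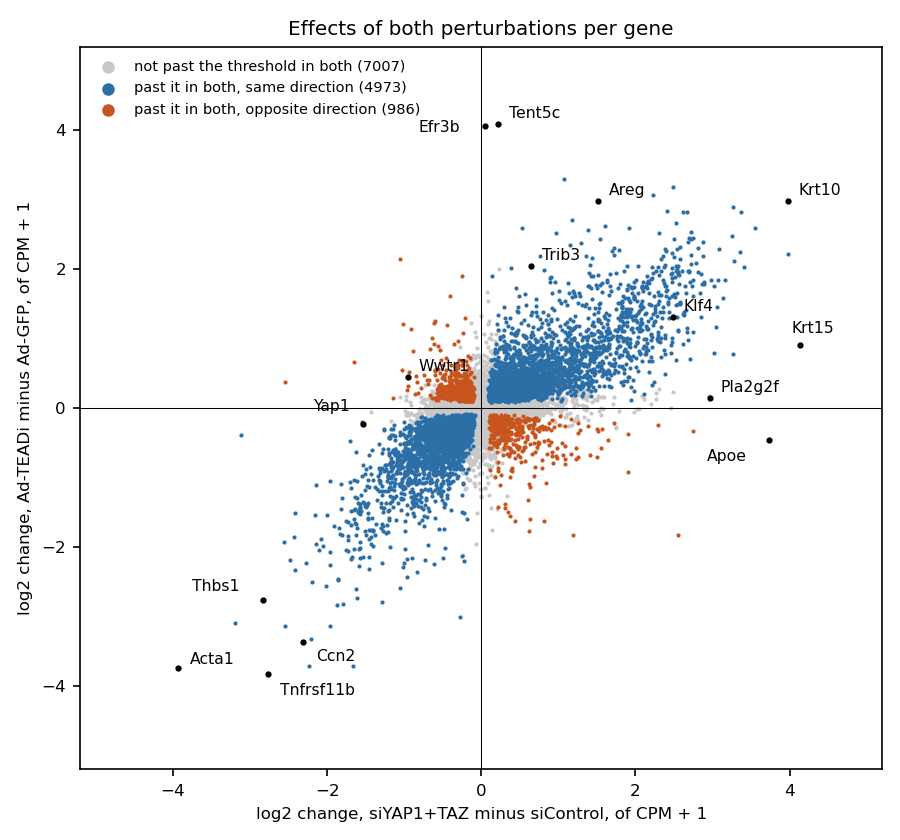
Log2 change with siYAP1+TAZ (x axis) against log2 change with Ad-TEADi (y axis), on the log2(CPM + 1) scale, with 1 point per gene tested (12966 genes), coloured by whether the gene passed in both comparisons and in which directions. Genes such as Acta1 (-3.94 and -3.75), Thbs1 (-2.84 and -2.76) and Krt10 (3.98 and 2.98) lie in the shared corners, while Yap1 (-1.54 and -0.23), Apoe (3.74 and -0.46) and Tent5c (0.22 and 4.09) lie away from them.

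Effects differed for 6673 genes: 3249 effects were higher and 3424 lower with siYAP1+TAZ than with Ad-TEADi (limma with Benjamini-Hochberg adjustment at 0.05), 436 and 89 of them by at least 2-fold. Scaling by column totals gave 2515 higher and 4658 lower. Among genes with a mean of at least 10 CPM, the largest positive differences were those of Apoe (chromosome 7, 19696109 to 19699188), Krt15, the metalloreductase gene Steap4 and the epidermal phospholipase gene Pla2g2f. Apoe rose by 3.74 with siYAP1+TAZ and fell by 0.46 with Ad-TEADi (from 208 to 152 CPM), a difference of 4.20 (SE 0.121; limma with Benjamini-Hochberg adjustment, adjusted p = 8.39e-15). Krt15 rose in both, with a difference of 3.23. Steap4 rose with siYAP1+TAZ and fell with Ad-TEADi, with a difference of 3.03. It stood at 5.25, 13.3, 25.5 and 6.45 CPM in siControl, siYAP1+TAZ, Ad-GFP and Ad-TEADi, so its controls differed too. Pla2g2f stood at 25.5, 207, 17.5 and 19.3 CPM in the same groups, with a difference of 2.83. Among the same genes, the largest negative differences were those of the prolactin family genes Prl2c2 (-2.92), Prl2c3 (-2.74) and Prl8a1 (-2.05) and the receptor gene Acvrl1 (-2.23), of which the Prl2c genes are uncertain because of near-identical copies. In the groups in that order Prl2c2 stood at 96.9, 15.8, 32.4 and 42.2 CPM and Prl2c3 at 227, 25.2, 98.6 and 75.4 CPM. The controls of both genes thus differed as well. The effects on the Hedgehog effectors Gli1 and Gli2, chosen for this comparison after their values were seen, were higher with siYAP1+TAZ by differences of 0.99 and 0.76 (limma with Benjamini-Hochberg adjustment, adjusted p = 1.13e-06 and 7.78e-07), while the level of Gli1 was 8.42 CPM in siYAP1+TAZ and 9.32 CPM in Ad-TEADi, and 3.64 and 9.08 CPM in their controls.

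By list, 6 had higher and 3 lower effects with siYAP1+TAZ than with Ad-TEADi. Effects on differentiation genes were higher with siYAP1+TAZ. This held for 17 of 19 spinous genes (18 adjusted over the list alone; camera, adjusted p = 1.84e-07, and adjusted p = 0.271 with an estimated correlation). It held for 21 of 32 cornified envelope genes, with 4 the other way (camera, adjusted p = 0.000137, and adjusted p = 0.623 with an estimated correlation). It also held for 14 of 19 lipid barrier genes (camera, adjusted p = 3.61e-05, and adjusted p = 0.271 with an estimated correlation). The loricrin gene Lor, chosen after its values were seen, rose by 2.01 with siYAP1+TAZ and was at 5.52 ± 0.707 CPM in Ad-GFP and 5.50 ± 1.28 CPM in Ad-TEADi, a difference of 2.03. The effect was also higher for 10 of 15 interferon response genes (11 adjusted over the list alone; camera, adjusted p = 0.00014, and adjusted p = 0.134 with an estimated correlation). The same was measured for 11 of 18 WNT pathway genes (camera, adjusted p = 0.000298, and adjusted p = 0.106 with an estimated correlation) and 11 of 15 hair follicle progenitor genes, with 1 lower (12 and 1 adjusted over the list alone; camera, adjusted p = 0.000288, and adjusted p = 0.1 with an estimated correlation). It was lower for all 30 mitosis genes (camera, adjusted p = 2.22e-12, and adjusted p = 0.27 with an estimated correlation). It was lower for 28 of 30 DNA replication genes (29 adjusted over the list alone; camera, adjusted p = 9.87e-12, and adjusted p = 0.106 with an estimated correlation) and 17 of 22 stress response genes, with 1 higher (camera, adjusted p = 4.29e-07, and adjusted p = 0.271 with an estimated correlation). The members on the other side, named after their values were seen, were Lce3c (-0.58), Lce3d (-0.67), Sprr2d (-1.43) and Sprr2h (-0.44), all with near-identical copies, Cd34 (-0.60) and Slc7a11 (0.70). The other lists tested did not pass (camera, adjusted p from 0.0815 to 0.871). The lowest was that of the Hedgehog pathway list, which passed when columns were scaled by their totals (camera, adjusted p = 0.0488, in a range of 0.0488 to 0.156 over the alternatives).

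**Figure D3:**
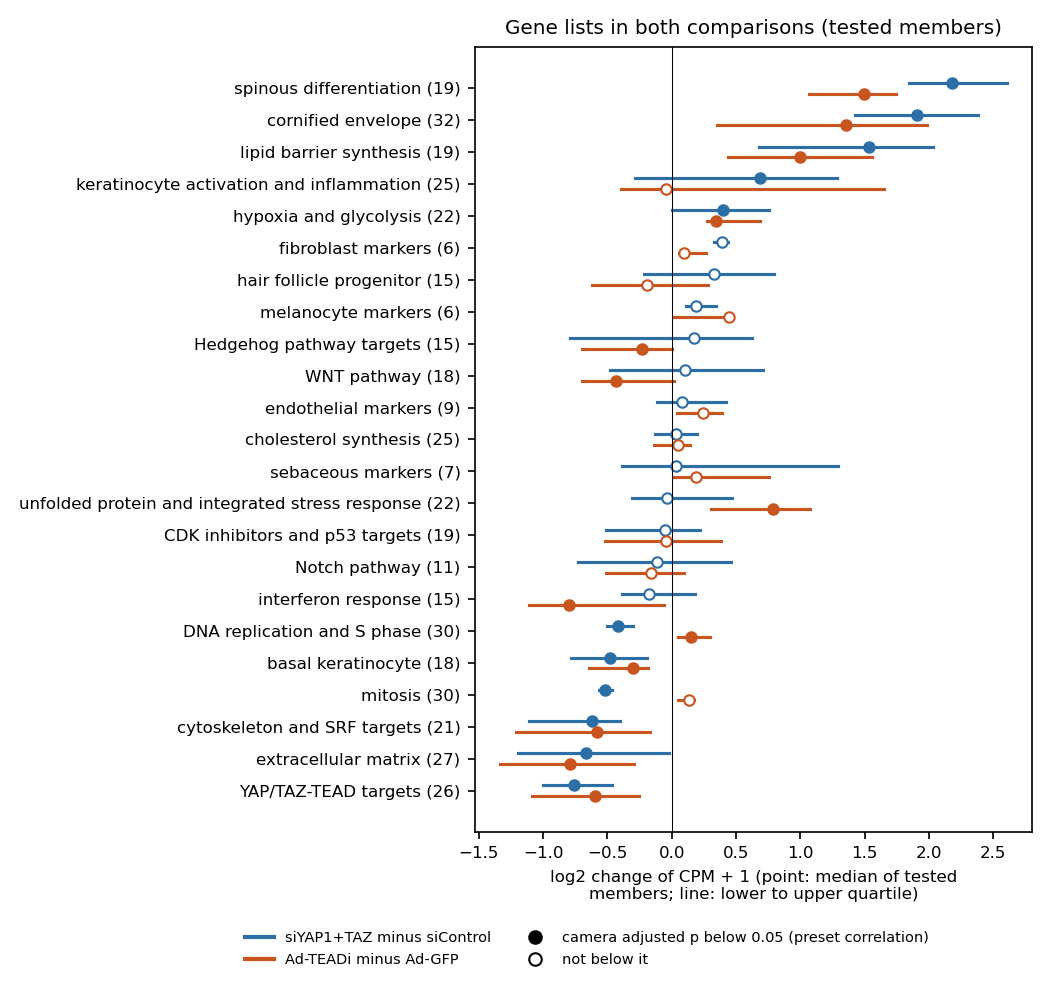
Median log2 change of the 23 tested gene lists on the log2(CPM + 1) scale with siYAP1+TAZ against siControl and with Ad-TEADi against Ad-GFP. Points are medians over a list's tested genes, bars run from the lower to the upper quartile, and filled points passed camera at an adjusted p under 0.05; the mitosis list stands at -0.51 and 0.13.

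The background between the experiments was taken from the controls, since delivery by lipid-carried RNA or by adenovirus is confounded with them. Ad-GFP and siControl libraries differed by 2421 genes higher and 2823 lower in Ad-GFP (limma with Benjamini-Hochberg adjustment at 0.05), 81 and 51 of them by at least 2-fold. Scaling by column totals turned this balance, with 3193 higher and 2216 lower. Apoe was higher in Ad-GFP (208 ± 8.88 against 36.5 ± 4.38 CPM, log2 difference 2.49), as were the glutamine synthetase gene Glul (2.33) and Mill1 (2.16). The metalloprotease gene Mmp3 (-2.07), Areg (-1.66) and Trib3 (-1.65, 16.1 ± 3.11 against 52.4 ± 4.25 CPM) were lower. Gli1, Gli2 and Ptch1 were higher in Ad-GFP, by 1.12, 0.49 and 0.84, and were chosen for this comparison after their values were seen.

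The Hedgehog pathway list was higher in Ad-GFP, with 10 of 15 genes higher and 2 lower (camera, adjusted p = 6.6e-05, and adjusted p = 0.0409 with an estimated correlation). So were DNA replication and S phase, with 27 of 30 higher (28 adjusted over the list alone; camera, adjusted p = 5.91e-14, and adjusted p = 0.0497 with an estimated correlation), and the WNT pathway, with 13 of 18 higher and 2 lower (15 and 2 adjusted over the list alone; camera, adjusted p = 3.45e-05, and adjusted p = 0.0497 with an estimated correlation). Mitosis was higher in 27 of 30 genes (camera, adjusted p = 3.74e-09, and adjusted p = 0.331 with an estimated correlation). The interferon response was higher in 8 of 15 genes and lower in 2 (9 and 2 adjusted over the list alone; camera, adjusted p = 0.00483, and adjusted p = 0.233 with an estimated correlation), and did not pass without Ad-GFP A (0.117) or Ad-GFP B (0.0539) or at a mean of at least 5 CPM (0.0917), in a range of 0.0012 to 0.117 over the alternatives. Hair follicle progenitor genes were higher in 9 of 15 and lower in 2 (camera, adjusted p = 0.0232, and adjusted p = 0.161 with an estimated correlation), and did not pass without Ad-GFP B (0.052) or at a mean of at least 5 CPM (0.202), in a range of 0.0111 to 0.202. All 22 stress response genes were lower in Ad-GFP (camera, adjusted p = 1.16e-13, and adjusted p = 0.141 with an estimated correlation). Also lower were 14 of 19 spinous genes, with 2 higher (15 and 2 adjusted over the list alone; camera, adjusted p = 0.00168, and adjusted p = 0.524 with an estimated correlation). Lower too were 27 of 32 cornified envelope genes, with 2 higher (camera, adjusted p = 3.37e-07, and adjusted p = 0.381 with an estimated correlation) and 15 of 19 lipid barrier genes, with 2 higher (15 and 3 adjusted over the list alone; camera, adjusted p = 0.000113, and adjusted p = 0.331 with an estimated correlation). Cholesterol synthesis was lower in 14 of 25 genes and higher in 2 (16 and 2 adjusted over the list alone; camera, adjusted p = 0.000623, and adjusted p = 0.196 with an estimated correlation). Hypoxia and glycolysis was lower in 13 of 22 genes, with 1 higher (13 and 2 adjusted over the list alone; camera, adjusted p = 0.00168, and adjusted p = 0.381 with an estimated correlation), and in 10, with 3 higher, under column totals. Members on the other side of these lists, named after their values were seen, included Cdon (-0.25), Snai2 (-0.17), Lgr6 (-0.89), Wnt5a (-0.87), Mx1 (-0.48), Mx2 (-0.30), Plet1 (-0.24), Runx1 (-0.10), Krt1 (0.24), Pou3f1 (0.43), Sprr2a1 (0.68), Sprr2a3 (0.80), Asah1 (0.29), Elovl6 (0.28), Ebp (0.24) and Aldoc (0.54). The other lists did not pass (camera, adjusted p from 0.0675 to 0.979). The lowest was that of keratinocyte activation and inflammation, with 14 of 25 genes lower and 6 higher (15 and 6 adjusted over the list alone). It passed under several alternatives, such as a mean of at least 5 CPM (camera, adjusted p = 0.00598) and column totals (0.0198), in a range of 0.00598 to 0.128.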

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

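The gene lists below are those whose effects differed between siYAP1+TAZ and Ad-TEADi in the planned test of the difference, and the splits of the samples were planned too. With an estimated correlation camera called 0 lists for the difference (lowest adjusted p = 0.1; 4 lists at an unadjusted p under 0.05), while fry called 10 higher and 6 lower. The tests of the control groups, of the column scaling and of weaker inhibition by Ad-TEADi with its bound, and the splits with the difference between the experiments removed, were chosen only after the results had been seen.

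Cell cycle genes moved apart, with a median difference of the effects of -0.65 for mitosis and -0.57 for DNA replication and S phase. Over these 60 genes the median log2 change was -0.47 with siYAP1+TAZ and 0.14 with Ad-TEADi (30 genes higher and 1 lower). A bound was set for a weaker inhibition by Ad-TEADi that reduces these genes' changes in proportion to those of the targets. At the lower quartile of the targets' ratio (0.564) the median would be -0.27. The lower quartile measured was 0.053, or 0.030 (median of ratios), -0.033 (quantile normalization) and -0.042 (column totals, where -0.34 would be needed). This argues only against a proportional reduction of that size or milder. Whether cell cycle genes respond in proportion to the targets was not tested, so a weaker inhibition stays open. A difference between the control groups alone is argued against by its sign. Ad-GFP lay 0.32 above siControl, which by itself would make the difference of the effects positive. Compared directly, siYAP1+TAZ lay below Ad-TEADi by a median of -0.92 (quartiles -0.998 to -0.86), in all 60 genes. This is not separate evidence: per gene, it equals the difference of the effects minus the control difference. It also includes the difference in delivery. Under the 3 other scalings the value nearest to 0 was -0.59, with quantile normalization. These scalings moved the median difference over all genes by -0.085 (column totals), 0.020 (median of ratios) and -0.032 (quantile normalization). Shifts of that size could not bring the pattern near 0. The result shows only that the pattern did not hinge on the choice among these scalings. The mode of delivery, which is confounded with the experiments, and an action of YAP1 and TAZ that does not pass through TEAD may each account for the difference, and neither was tested.

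The unfolded protein and integrated stress response list rose with Ad-TEADi and not with siYAP1+TAZ, with a median difference of the effects of -0.72. All 22 of its genes were lower in Ad-GFP than in siControl, with a median of -0.59, and the treated libraries compared directly differed by a median of -0.073 (quartiles -0.34 to 0.04). A difference between the control groups could therefore account for the pattern, and it is a candidate explanation from the same data. Under the 3 other scalings the value nearest to 0 was -0.70, with scaling by the median of ratios. The shifts these scalings make, given above, were too small to bring it near 0. The pattern thus did not hinge on the choice among these scalings, and no more is shown. What lowers these genes in Ad-GFP, such as virus or lipid carrier, was not tested.

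Differentiation genes rose further with siYAP1+TAZ, with a median difference of the effects of 0.79 for the spinous and 0.48 for the cornified envelope list. A difference between the control groups alone is argued against by its sign: Ad-GFP lay below siControl, by medians of -0.35 (spinous) and -0.65 (cornified). By itself this would make the differences of the effects negative. Compared directly, siYAP1+TAZ lay above Ad-TEADi by medians of 1.03 (spinous, quartiles 0.91 to 1.37) and 1.14 (cornified, quartiles 0.64 to 1.69). That comparison follows from the same values, so it is not separate evidence. Under the 3 other scalings the values nearest to 0 were 0.65 for spinous with quantile normalization and 0.39 for cornified with column totals (lower quartile 0.20). The shifts these scalings make were too small to bring either near 0. The patterns thus did not hinge on the choice among these scalings, and no more is shown. A weaker inhibition by Ad-TEADi stays open: over the 22 YAP/TAZ-TEAD targets that fell with siYAP1+TAZ the ratio of the Ad-TEADi to the siYAP1+TAZ change had a median of 0.960 (quartiles 0.564 to 1.203), against medians of 0.636 for spinous and 0.731 for cornified genes, too wide a spread to decide. The mode of delivery and a biological difference between partial knockdown of the coactivators and inhibiting TEAD may also account for it, and neither was tested.

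The other lists whose effects differed had median differences of 0.36 (lipid barrier synthesis), 0.49 (interferon response), 0.33 (WNT pathway) and 0.37 (hair follicle progenitor). Ad-GFP lay above siControl by medians of 0.29 (interferon response), 0.28 (WNT pathway) and 0.19 (hair follicle progenitor). For lipid barrier synthesis it lay below, at -0.37, opposite in sign to that list's pattern. A difference between the control groups could therefore account for part of the interferon, WNT and hair follicle patterns. As list means, the difference of the effects was 0.65 (interferon response), 0.48 (WNT pathway) and 0.64 (hair follicle progenitor). The control difference was 0.27, 0.29 and 0.26 in the same order. The treated libraries were not compared directly for these lists.

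The 6 libraries of a comparison allow 10 splits, too few for a share under 0.05. In limma with Benjamini-Hochberg adjustment the real split gave 8932 genes for siYAP1+TAZ, 7754 for Ad-TEADi and 5244 for the controls, in each case the 1 split of 10 with as many. The highest of the others gave 0 each time (297, 703 and 880 genes at an unadjusted p under 0.05). For the difference of the effects the real split gave 6673 genes and the highest other of 100 drawn from 200 gave 4763, with siControl C, Ad-GFP A and Ad-GFP B as 1 set of controls. These splits decide nothing, since mixing experiments whose controls differ widens the spread within groups (median SD 0.103 or more, against 0.0777 in the real split). With the mean difference between the experiments removed from every gene, the real split gave 6651 genes and the highest other of the 100 drawn gave 1088. This argues against a chance assignment of single libraries only. The libraries of a group may share a culture, so a chance difference between cultures cannot be excluded. Nor can a technical difference between the experiments.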

How the results depend on the processing

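The alternatives were planned, except that for the gene lists the tests with a pseudocount of 5 CPM, no filter, the median of ratios, eBayes without trend, robust eBayes and array weights were chosen after the data had been seen. Of 462 values of counts and overlaps under the alternatives, 445 stayed within the limits set for them and 17 moved. Of 4448 values of named genes, 4429 kept their side of the threshold, 18 fell short of it and 1 reversed. Of 2288 values of gene lists, 2198 kept theirs, 50 fell short (42 of them with an estimated correlation) and 40 passed newly (26 of them with fry). Those that kept their side kept their direction, except 5 gene and 49 list values that differed in sign while neither passed. At a mean of at least 5 CPM, 20 named-gene values and 3 lists gave no value. The count models planned for recovered whole reads were not run, since fewer than 95% of low values were whole multiples.

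Scaling by column total gave 2822 genes higher and 7159 lower with siYAP1+TAZ, 1780 higher in both comparisons and 3708 lower in both, because its construction moves the median of all genes by -0.17 with siYAP1+TAZ and by -0.09 with Ad-TEADi. It also took Ptch1 with siYAP1+TAZ to -0.0062. Restricting the genes to a mean of at least 5 CPM raised the Pearson correlation of the effects to 0.74, with fewer genes tested. Leaving out each library in turn gave -0.24 to -0.14 for Tead4 with siYAP1+TAZ, which no longer passed without siControl C (-0.14) or siYAP1+TAZ C (-0.14). The cause was not tested. The numbers of genes higher and lower ran from 3925 to 4272 and 4313 to 4720 for siYAP1+TAZ, from 3960 to 4379 and 3128 to 3438 for Ad-TEADi, from 2954 to 3199 and 3060 to 3376 for the difference, and from 1982 to 2461 and 2298 to 2860 for the controls. Of the genes called with all libraries, 91.7% to 99.5%, 90.01% to 99.6%, 89.0% to 93.9% and 81.3% to 99.1% were still called in the same direction, and 0 changed sign.

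With a correlation estimated from the libraries, camera called 0 lists higher and 0 lower for siYAP1+TAZ, 0 and 0 for Ad-TEADi and 0 and 0 for the difference (5, 7 and 4 lists at an unadjusted p under 0.05), and 3 higher and 0 lower for the controls. The cause was not tested. With fry, which does not compare a list with other genes, 11 lists were higher for siYAP1+TAZ, 11 for Ad-TEADi and 10 for the difference, with 6 lower for the difference. Its construction, which asks only whether a list moved, gives the higher counts. With fry set apart, hair follicle genes passed with siYAP1+TAZ only under column totals (camera, adjusted p = 0.0424, in a range of 0.0424 to 0.585) and the cytoskeleton list in the controls only under quantile normalization (0.0411, in a range of 0.0411 to 0.141).

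The replicate letters paired the samples at most in part. For A, B and C, same-lettered libraries deviated together with correlations of -0.0033, 0.12 and 0.046 (siControl and siYAP1+TAZ) and -0.046, 0.27 and 0.25 (Ad-GFP and Ad-TEADi). The value was above 0.1, and the best match had the same letter, for B in both experiments and for C with adenovirus. For the other letters neither held. A difference shared by libraries of a letter can therefore not be excluded. With the letter as a replicate block, 4296 genes were higher and 4765 lower for siYAP1+TAZ, 4436 and 3481 for Ad-TEADi, 3328 and 3519 for the difference and 2493 and 2939 for the controls. Each of these counts was above that without the block. The block changed no call of a named gene and, among lists, let mitosis with Ad-TEADi (adjusted p = 0.0439, camera, in a range of 0.026 to 0.32 over the alternatives) and keratinocyte activation in the controls (0.0413, in a range of 0.00598 to 0.128) pass. How far a depth of 20.02 M reads or more per library limits genes near 1 CPM was not tested. In simulated data for siYAP1+TAZ, 76% of 1.2-fold changes were recovered, all in genes with a siControl mean of at least 5 CPM.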

Other observations

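Further genes, chosen after their values were seen, moved within and across the lists. Uox, Tcf23 and Cyp2b10 rose with both treatments, by log2 changes of 3.98 and 2.21, 2.48 and 3.19, and 2.22 and 3.07 (siYAP1+TAZ, then Ad-TEADi), and Csf1 fell with both, by 1.67 and 3.72. Outside the rule for the difference, Tent5c and Efr3b rose with Ad-TEADi and stood at 0.366 ± 0.0184 and 0.466 ± 0.0426 CPM in siYAP1+TAZ, with differences of the effects of -3.87 and -4.01 (limma with Benjamini-Hochberg adjustment, adjusted p = 1.66e-13 and 1.54e-12). Among Notch pathway genes, the ligand genes Dll1 (-0.79 and -0.61), Jag1 (-0.85 and -0.41) and Jag2 (-0.46 and -0.21) fell with both treatments, while the receptor gene Notch3 and the feedback gene Nrarp (0.81 and 0.77) rose with both. The hair follicle stem cell gene Lgr5 and the WNT antagonist gene Apcdd1 moved opposite ways, at 1.26 and -0.71, and at 0.81 and -1.62, with differences of 1.97 and 2.44, although Lgr5 was low, at 2.46 CPM in siYAP1+TAZ. The basal keratin gene Krt14 was at 14887 ± 259 CPM in siControl and 16311 ± 456 CPM in siYAP1+TAZ, a log2 change of 0.13 that did not pass (limma with Benjamini-Hochberg adjustment, adjusted p = 0.105), and Krt5 fell by 0.28 with siYAP1+TAZ and by 0.22 with Ad-TEADi. The proliferation gene Mki67 fell by 0.39 with siYAP1+TAZ and was at 0.14 with Ad-TEADi (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0561).

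Mitochondrial genes took 3.11%, 3.18%, 3.47% and 3.17% of the column total in siControl, siYAP1+TAZ, Ad-GFP and Ad-TEADi, ribosomal protein genes 4.54%, 4.40%, 4.29% and 4.65%, and the 10 most abundant genes 10.2%, 11.3%, 10.3% and 10.2%. Xist stood at 376 ± 17.7, 405 ± 9.16, 379 ± 6.12 and 450 ± 13.3 CPM in these groups, and 4 Y-linked genes together at 10.5, 14.4, 9.19 and 10.5 CPM.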
